A study of Drosophila melanogaster with 10 samples.

How the data were processed

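RNA of sorted central brain neuroblasts of Drosophila melanogaster was profiled in 10 samples of 3 groups: wild-type larvae (2 samples), wild-type pupae (4) and med27 RNAi pupae (4). Per the labels, every group carried inscuteable-Gal4 and membrane-bound GFP, and wild type here means flies with the empty landing site of the RNAi collection in place of the construct. Per the labels' protocols, eggs were laid for 24 h at 29 °C, animals were reared for 5 days (larvae) or 6 days (pupae, taken at 0 to 2 h), large cells with high GFP were sorted by flow cytometry, and libraries were made from about 1 µg of Trizol-extracted total RNA by polyA selection and a dUTP method that keeps the strand. The labels describe 2 biological replicates per group, and for the pupal groups 2 technical runs of each. Run pairs correlated at r = 0.9987 to 0.9991 over expressed genes, with an SD of the log2 difference of 0.0832 to 0.104, and were averaged on the FPKM scale, so that n = 2 in each group and p-values measure the spread between these 2.

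The authors deposited FPKM per gene for each run (fragments scaled to transcript length and to mapped fragments), a normalized unit and not a count, as Cufflinks gene tables with confidence bounds, per the file headers. The submitters' processing notes name BWA 0.6.1, TopHat 1.4.1, Cufflinks 1.3.0, HTSeq and DESeq 1.8.3 without a role or order, and the genome build and annotation are not given in the sources used here. Coordinates are those of the deposited tables, counted from 1, and no build is named for them. The authors also deposited the tables of 2 DESeq comparisons that hold genes with an adjusted p-value below 0.01, per the file headers and values. In these tables the base means are a signal made by the authors by dividing read counts by size factors, the fold change is the authors' ratio of base means, and the log2 fold change is the authors' log2 of that ratio. Which runs entered them is not given in the sources used here. The log2 values of the RNAi table are of wild-type over RNAi pupae, and their signs were turned here to give RNAi against wild-type pupae. From these tables only counts of genes, signs and fold changes of named genes were taken. Counting by strand is not stated, so values of overlapping genes are uncertain, as are those of near-identical copies.

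The deposited FPKM carry no counts, but the upper confidence bounds give the fragments behind a value. They implied 18200537 and 18070378 fragments for the larval libraries and 27127121 to 31192332 per pupal run, and 92.2 to 94.19% of values under 50 fragments in single-isoform genes then lay within 0.02 of a whole number. Larval values therefore carry more counting error. The FPKM of a run summed to 6.76e+05 to 8.141e+05, of which CR34335 alone took 7.049 to 10.68%. Count-based tests were not run, since the tables hold FPKM.

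Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend, two-sided. One fit held all 3 groups, which share 1 estimate of the spread (3 residual degrees of freedom, 4.28 prior). The 6992 genes with a mean FPKM of at least 1 over the 6 replicates were kept of 14210 listed, and p-values were adjusted by Benjamini-Hochberg over them, with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. A gene listed at 0 can be a failed estimate, so such genes are given per library, without a fold. The 3 comparisons were: pupal with larval wild type, med27 RNAi with wild-type pupae, and med27 RNAi pupae with larval wild type. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. With 2 replicates per group no test of an outlying sample was made.

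Before the data were examined, 29 gene lists, the tests, the filter, the rule for named genes and all alternatives but the added ones named below were fixed. The lists were respiratory complexes I to V (complex III with cytochrome c), the tricarboxylic acid cycle with pyruvate dehydrogenase, glycolysis with lactate dehydrogenase, the pentose phosphate pathway, fatty acid oxidation and lipolysis, mitochondrial ribosomal proteins, mitochondrial biogenesis regulators, cytosolic ribosomal proteins, ribosome biogenesis, insulin and TOR signalling, cell cycle, ecdysone response, Mediator subunits, neuroblast identity, temporal factors, autophagy, apoptosis, heat shock and stress, RNA interference machinery, and markers of neurons, glia, haemocytes, fat body, intermediate progenitors and optic lobe. The 27 lists with at least 3 kept members were tested by camera with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation, with which 0 lists passed in any comparison (smallest adjusted p = 0.371, 0.465 and 0.77 with an estimated correlation for the 3 comparisons in turn). Members not matched by name were mtTFB1 and qm, the latter another name of RpL10.

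Named genes followed a rule with 4 parts: MED27 in every library; for pupal against larval wild type and for med27 RNAi against wild-type pupae, the 10 largest increases and decreases among called genes with a mean of at least 5 FPKM whose replicates did not overlap; up to 4 members with the smallest p from each list; and, whatever their result, EcR, Eip75B, br, Imp, Syp, chinmo, dpn, mira, ase, pros, grh, ImpL3, InR, dm, stg and CycE. Of the list members so named, the report prints a part, chosen after their values were seen. Hml, repo, Lsp2, CG2182, tio, ade3, ade5, roX1 and the neighbours of MED27 stand outside the rule and were likewise picked after values were seen.

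The relation between the stage change and the RNAi change was measured by Pearson's r and the covariance across genes. Beside these stand 100 simulated data sets without group effects that share the wild-type pupal libraries, with noise independent between genes. It was planned to judge the relation by r, and the covariance was preferred after r had been seen, since r lay above all simulated values. Overlaps of calls are given beside those of independent lists of the same sizes.

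Alternatives were a pseudocount of 0.1 or 5, no filter on low values, a minimum of 5 FPKM, median-of-ratios scaling, quantile normalization, only the compared groups in the fit, the replicate number as a block, either technical run alone, leaving out each replicate in turn (a lone sample is then assumed to vary like the others), and a false discovery rate of 0.01. After the data had been seen, 2 alternatives were added: leaving out genes with a failed or low-data estimate in any library (6938 genes kept), and removing a trend with transcript length. For the latter, a lowess curve (span 0.3, 3 iterations) of each gene's deviation from its mean on its log2 transcript length was subtracted in each library. Lengths came from a reference annotation in which 13575 of the 14210 genes matched by identifier, 416 by symbol and 219 not at all, and 6950 of the tested genes had a length. All tested members of every list had one. Whether the trend came from library preparation or RNA quality was not tested, and no check of GC content was run.

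The fit was checked on simulated data in which 200 genes were changed. At a change of 0.5, 1 and 2 on the log2 scale, limma called 67.2%, 95.5% and 98.5% of the changed genes for pupal against larval wild type, with 4.4% of its calls among unchanged genes. For med27 RNAi against wild-type pupae these shares were 58.2%, 95.5% and 98.5%, with 5.62% of calls unchanged, and for med27 RNAi against larvae 64.2%, 95.5% and 98.5%, with 7.53%.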

Results

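Neuroblasts, the neural stem cells of the fly, were sorted from Drosophila melanogaster central brains and profiled by stranded sequencing of polyA RNA in 3 groups. The groups were wild-type late larvae, wild-type pupae of 0 to 2 h, and pupae of the same age in which inscuteable-Gal4, a neuroblast driver, expressed an RNA interference (RNAi) construct against med27, the gene of a subunit of the Mediator complex, which links transcription factors to RNA polymerase II. Sorted cells were large and strongly positive for membrane-bound GFP. Each group held 2 biological replicates, and the 2 technical runs of each pupal replicate were averaged, so n = 2 per group throughout. Error bounds implied 18200537 and 18070378 larval fragments and 27127121 to 31192332 per pupal run. Between 6806 and 7087 genes reached 1 FPKM in a run. Levels are given in FPKM as mean ± SD, and changes as log2 fold changes of FPKM + 1 with their SE from limma over 6992 genes. Gene symbols are those of the deposited files, with the current symbol in brackets where it helps, and p-values were adjusted by the Benjamini-Hochberg method.

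The targeted gene, MED27 (FBgn0037359, 3R 1480867 to 1482058, a protein-coding gene whose end overlaps CG2182 by position), checks the labels. It stood at 31.7 and 38.3 FPKM in the larval libraries, at 31.5 and 27.4 in the wild-type pupal libraries and at 5.33 and 3.99 in the med27 RNAi libraries. MED27 fell in RNAi pupae by comparison with wild-type pupae, with a log2 fold change of -2.43 (SE 0.15, limma adjusted p = 0.000522). Larval and pupal wild-type libraries did not pass the test for a difference in MED27 (-0.24, limma adjusted p = 0.215).

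The comparison of pupal with larval wild-type neuroblasts asked which transcripts change in these stem cells at the onset of metamorphosis, which a pulse of the steroid hormone ecdysone sets off. Ecdysone-response genes and the temporal factors of neuroblasts rose. Hr4 (FBgn0263775, X 1835973 to 1899495), an ecdysone-induced nuclear receptor, rose from 2.51 ± 0.0931 FPKM in larvae to 29.2 ± 1.98 in pupae (n = 2 per group), a log2 fold change of 3.11 (SE 0.11, limma adjusted p = 9.14e-05). Eip75B (FBgn0000568, 3L 17944508 to 18057721), which encodes the nuclear receptor E75, rose from 13.7 ± 3.87 to 47.3 ± 5.53 FPKM, by 1.74 (SE 0.19, limma adjusted p = 0.00157). ImpE2 and ImpE1, first known as ecdysone-inducible genes of imaginal discs, rose by 1.55 (limma adjusted p = 0.00244) and 1.55 (limma adjusted p = 0.00452). In the ecdysone list, 11 of 15 tested members were higher and 0 lower (11 and 1 adjusted over the list alone), with a median of 0.77, a camera adjusted p of 0.000455, and adjusted p = 0.371 with an estimated correlation. The receptor gene EcR itself stood at 6.76 ± 0.575 FPKM in larvae and 5.54 ± 0.652 in pupae and did not pass (-0.25, limma adjusted p = 0.186), although it passed in the other direction from its list, at -0.75 (limma adjusted p = 0.00672), once a trend with transcript length was removed from each library.

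Of the temporal factors, transcription factors and RNA-binding proteins whose levels change with neuroblast age, 7 of 8 tested rose and 0 fell (7 and 0 adjusted over the list alone). Their median was 1.03, the camera adjusted p was 0.000455, and the list had adjusted p = 0.371 with an estimated correlation. The zinc-finger gene mamo rose by 1.68 (SE 0.23, limma adjusted p = 0.00198) and chinmo (FBgn0086758, 2L 1651260 to 1704682) by 1.35 (SE 0.17, limma adjusted p = 0.00187), from 6.68 ± 1.4 to 18.6 ± 3.62 FPKM. CG17838 (Syp), an RNA-binding protein gene, rose from 1347 ± 493 to 3069.7 ± 207 FPKM, by 1.24 (SE 0.23, limma adjusted p = 0.00489). The nuclear receptor gene svp (FBgn0003651, 3R 8084471 to 8128507) rose by 1.10 (limma adjusted p = 0.00131), br, which encodes the Broad transcription factors, by 0.97 (limma adjusted p = 0.00548), and Imp by 0.97 (limma adjusted p = 0.0155). With the length trend removed the median was 0.67 for the temporal list, with 5 members higher and 0 lower, and 0.57 for the ecdysone list, with 7 higher and 1 lower, at adjusted p = 0.55 and 0.537 with an estimated correlation. Neuron markers, with a median of 1.17, rose over the same comparison as both lists. Both br and Eip93F belong to the ecdysone and the temporal list. The call of Imp also ended with the length trend removed (0.60, limma adjusted p = 0.086). Imp lost its call without larval replicate 2 (limma adjusted p = 0.0719) and wild-type pupal replicate 2 (0.0635).

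Genes of neuroblast identity and asymmetric division mostly rose from larva to pupa. In this list, 13 of 20 tested members were higher and 1 lower (13 and 1 adjusted over the list alone), with a median of 0.57 (0.22 with the length trend removed, where 7 were higher and 1 lower), a camera adjusted p of 1.32e-05, and adjusted p = 0.371 with an estimated correlation. Neuron markers rose more over the same comparison, with a median of 1.17. The growth repressor gene brat rose by 1.00 (limma adjusted p = 0.00199), the zinc-finger gene klu by 0.90 (limma adjusted p = 0.00152), grh by 0.78 (limma adjusted p = 0.00325) and the proneural gene ase (FBgn0000137, X 354533 to 357209) by 0.67 (limma adjusted p = 0.0027). The differentiation factor gene pros rose by 1.13 (limma adjusted p = 0.00186) and N (Notch) by 0.90 (limma adjusted p = 0.0018), but both calls ended with the length trend removed, at 0.04 (adjusted p = 0.711) and 0.02 (adjusted p = 0.849). The neuroblast genes mira and dpn did not pass, at 0.20 (limma adjusted p = 0.0788) and 0.11 (limma adjusted p = 0.282). Markers of intermediate progenitors rose in 6 of 7 tested members and fell in 0 (6 and 0 adjusted over the list alone), with a median of 0.63 and a camera adjusted p of 0.00282, and had adjusted p = 0.371 with an estimated correlation. Of these, pnt rose by 0.99 (limma adjusted p = 0.00186), btd by 0.72 (limma adjusted p = 0.00608), opa by 0.79 (limma adjusted p = 0.0151) and ey by 0.53 (limma adjusted p = 0.00815). Among optic lobe markers, 3 of 6 tested members were higher and 0 lower (4 and 0 adjusted over the list alone), with a camera adjusted p of 0.0175 and adjusted p = 0.371 with an estimated correlation. Here hth rose by 1.51 (limma adjusted p = 0.00172) and vvl by 1.48 (limma adjusted p = 0.00157). opa lost its call without larval replicate 1 (limma adjusted p = 0.0554) and wild-type pupal replicate 2 (0.0827). ey no longer passed without wild-type pupal replicate 2 (limma adjusted p = 0.0538).

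Cell cycle genes went both ways, with 8 of 31 higher and 10 lower (8 and 11 adjusted over the list alone). Their median was -0.12, their mean 0.03 and the camera adjusted p 0.939, with the test pointing down. CycE rose by 0.93 (limma adjusted p = 0.00187), E2f (E2f1) by 0.93 (limma adjusted p = 0.00265) and stg, the Cdc25 phosphatase gene that drives entry into mitosis, by 0.44 (limma adjusted p = 0.0127), while mus209 (PCNA), the sliding clamp of DNA replication, fell by 0.48 (limma adjusted p = 0.00553). Insulin and TOR signalling genes were higher in 7 of 15 members and lower in 0 (7 and 0 adjusted over the list alone), with a median of 0.39, a camera adjusted p of 0.000963 and adjusted p = 0.371 with an estimated correlation. The insulin receptor gene InR rose from 6.15 ± 1.93 to 21.2 ± 0.436 FPKM, by 1.66 (limma adjusted p = 0.00203), Akt1 by 0.88 (limma adjusted p = 0.00223), foxo by 0.87 (limma adjusted p = 0.00331) and S6k by 0.85 (limma adjusted p = 0.00174). The list's call ended with the length trend removed, at a median of 0.17 and a camera adjusted p of 0.287, with 5 members higher and 3 lower. The growth regulator dm (Myc) rose by 1.47 (limma adjusted p = 0.00506), and its list of ribosome biogenesis genes had 4 of 14 members higher and 2 lower (2 and 1 adjusted over the list alone), at a camera adjusted p of 0.251. Removal of the length trend left mus209 at -0.16, where it no longer passed (limma adjusted p = 0.0904). stg lost its call without larval replicate 2 (limma adjusted p = 0.0659) and wild-type pupal replicate 2 (0.076).

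Genes of oxidative phosphorylation fell from larva to pupa. Of the complex I (NADH dehydrogenase) subunits, 0 of 32 rose and 30 fell (0 and 31 adjusted over the list alone), with a median of -0.54 and a camera adjusted p of 2.89e-10. All 4 complex II subunits fell (0 higher and 4 lower adjusted over the list alone), with a median of -0.53 and a camera adjusted p of 0.0153. In complex III with cytochrome c, 8 of 9 fell and 0 rose (8 and 0 adjusted over the list alone, camera adjusted p = 0.000614), in complex IV 9 of 9 (9 and 0, camera adjusted p = 0.000455) and in complex V, the ATP synthase, 10 of 13 (10 and 0, camera adjusted p = 0.000554). Each of these 5 lists had adjusted p = 0.371 with an estimated correlation. CG14482 (UQCR-6.4, FBgn0034245, 2R 13459601 to 13460287) of complex III fell from 1079 ± 91 to 495 ± 18.5 FPKM, a log2 fold change of -1.12 (SE 0.09, limma adjusted p = 0.00131). CoVIII (COX8) of complex IV fell by 0.95 (limma adjusted p = 0.00131), CG10219 (SdhD) of complex II fell by 0.83 (limma adjusted p = 0.00131), CG12400 (ND-B14.5B) of complex I fell by 0.77 (limma adjusted p = 0.00174), and Oscp (ATPsynO) of complex V fell by 0.73 (limma adjusted p = 0.00152). With a trend over transcript length removed CG12400 was at -0.34 and no longer passed (limma adjusted p = 0.0551).

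Mitochondrial ribosomal protein genes fell, and cytosolic ones fell as deposited, with the call of the list ended by quantile normalization. Among mitochondrial ribosomal proteins, 63 of 73 fell and 1 rose (67 and 1 adjusted over the list alone), with a median of -0.49, a camera adjusted p of 6.03e-14 and adjusted p = 0.371 with an estimated correlation. Among them mRpL34 (FBgn0083983, 2R 11986498 to 11986842) fell from 195 ± 13.7 to 69.9 ± 0.265 FPKM, a log2 fold change of -1.46 (SE 0.08, limma adjusted p = 0.000403). Of the cytosolic ribosomal proteins, 65 of 84 fell and 0 rose (72 and 0 adjusted over the list alone), with a camera adjusted p of 4.8e-11 and adjusted p = 0.521 with an estimated correlation, and their median of -0.44 came to -0.07 under quantile normalization, where the call ended (camera adjusted p = 0.166). RpL39 (FBgn0023170, 2R 19949376 to 19949952) fell from 4849 ± 442 to 2331 ± 306 FPKM, a log2 fold change of -1.06 (limma adjusted p = 0.00244). The mRNAs of these lists are short, and across all genes the change followed transcript length, with medians from -0.46 at up to 500 nt to 0.67 above 5000 nt. Per doubling of length, the deviation of a library from the gene means had a log2 slope of -0.12 and -0.20 in larvae and 0.0919 and 0.19 in wild-type pupae, and its cause was not tested. With that trend removed, medians were -0.18 for complex I, -0.37 for complex II, -0.23 for complex III and -0.12 for mitochondrial ribosomal proteins, with camera adjusted p from 0.00359 to 0.0302, but adjusted p from 0.537 to 0.587 with an estimated correlation. Far fewer members then passed, with 8 lower and 0 higher in complex I, 2 and 0 in complex II, 4 and 1 in complex III, and 18 and 2 among mitochondrial ribosomal proteins. The calls of complex IV, complex V and the cytosolic ribosomal proteins ended, at medians of -0.07, -0.09 and -0.06 and camera adjusted p of 0.345, 0.309 and 0.157, with 2, 3 and 13 members lower and 0, 1 and 1 higher.

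Glycolytic genes fell too, in 8 of 12 tested members, with 0 higher (9 lower and 0 higher adjusted over the list alone), a median of -0.59, a camera adjusted p of 0.0153 and adjusted p = 0.552 with an estimated correlation. Gapdh2 fell by 1.09 (limma adjusted p = 0.0049), Pglym78 fell by 0.87 (limma adjusted p = 0.00396), and PyK, the pyruvate kinase gene, a log2 fold change of -0.76 (limma adjusted p = 0.00471). ImpL3 (Ldh, FBgn0001258, 3L 6252592 to 6255793), the lactate dehydrogenase gene, stood at 10.9 and 18.6 FPKM in larvae and at 102 and 8.23 in wild-type pupae and did not pass (1.02, limma adjusted p = 0.394), and its log2 fold change was -0.73 without wild-type pupal replicate 1 and 2.76 without replicate 2. In the pentose phosphate pathway 5 of 7 genes fell and 0 rose (5 and 0 adjusted over the list alone), with a median of -0.52, a camera adjusted p of 0.0348 and adjusted p = 0.521 with an estimated correlation, and Tal (Taldo) fell by 0.76 (limma adjusted p = 0.00186). That call ended with the length trend removed (camera adjusted p = 0.102) and over genes of at least 5 FPKM (0.0611). The tricarboxylic acid cycle list did not pass (camera adjusted p = 0.119), with 2 higher and 8 lower of 17 (2 and 8 adjusted over the list alone), among them Idh, which fell by 0.91 (limma adjusted p = 0.00157). The pentose phosphate list lost its call without larval replicate 2 (camera adjusted p = 0.0652). The glycolysis list lost its call without wild-type pupal replicate 2 (camera adjusted p = 0.0777).

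**Figure D1:**
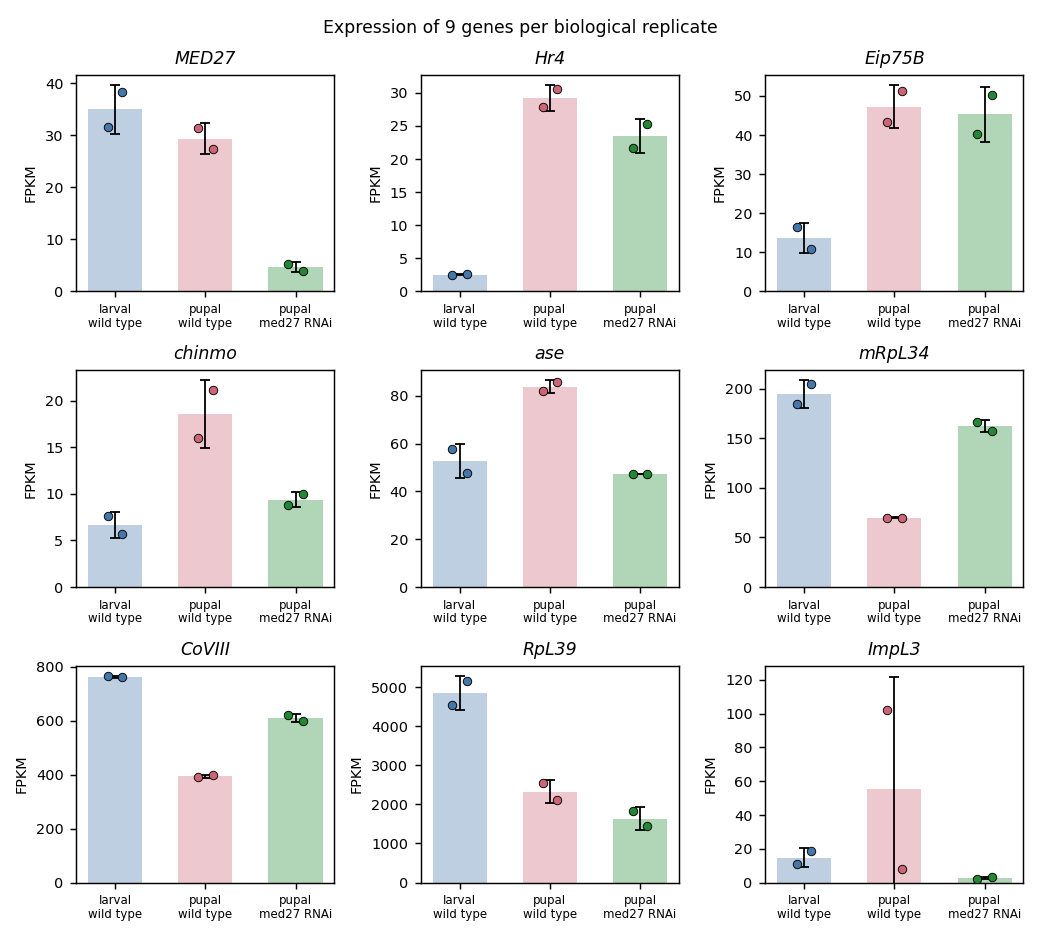
Each panel plots the FPKM of 1 gene on a linear axis from 0 for larval wild-type, pupal wild-type and pupal med27 RNAi neuroblasts, with points for the 2 biological replicates, a bar for their mean and a line for ± SD. MED27 fell in the RNAi libraries, Hr4 rose from larva to pupa, and mRpL34 was lower in wild-type pupae than in the other groups, at 69.9 against 194.7 and 162.2 FPKM.

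Smaller groups changed in part. Of the apoptosis genes 3 of 8 rose and 0 fell (3 and 0 adjusted over the list alone), at a camera adjusted p of 0.0348 and adjusted p = 0.371 with an estimated correlation (camera adjusted p = 0.0888 over genes of at least 5 FPKM), and the death gene grim rose by 1.10 (limma adjusted p = 0.00995). The stress list had 6 higher and 2 lower of 15 (6 and 2 adjusted over the list alone, camera adjusted p = 0.156). Hsp70Ba rose by 0.91 (limma adjusted p = 0.00132), though the Hsp70 genes are near-identical copies and their values uncertain, while Hsp23 fell by 0.65 (limma adjusted p = 0.00519). Of the Mediator subunits 5 rose and 10 fell of 29 (6 and 10 adjusted over the list alone, camera adjusted p = 0.691), including skd, which rose by 1.36 (limma adjusted p = 0.00132), and MED10, which fell by 0.54 (limma adjusted p = 0.00273). Fatty acid oxidation genes were higher in 1 and lower in 5 of 9 (1 and 5 adjusted over the list alone, camera adjusted p = 0.156), and the lipase gene bmm rose by 1.01 (limma adjusted p = 0.00448). Autophagy genes had 3 higher and 1 lower of 13 (3 and 1 adjusted over the list alone, camera adjusted p = 0.346). The RNA interference list had 2 higher and 1 lower of 6 (2 and 1 adjusted over the list alone, camera adjusted p = 0.731, median -0.08, mean 0.16, test up), with AGO1 up by 1.17 (limma adjusted p = 0.00244). Once the length trend was removed, there were 1 higher and 3 lower in this list, at a median of -0.25, 1 and 2 in the autophagy list and 5 and 4 among Mediator subunits. Dcr-1 was called in opposite directions, at 0.35 (limma adjusted p = 0.0174) as deposited and at -0.34 (limma adjusted p = 0.0259) without the trend. Regulators of mitochondrial biogenesis had 2 higher and 2 lower of 6 (2 and 2 adjusted over the list alone, camera adjusted p = 0.981, median -0.17, mean 0.09, test up). Spargel (srl), the fly PGC-1 gene, rose by 0.71 (limma adjusted p = 0.00397). Removal of the length trend ended the calls of Hsp23 (-0.30, limma adjusted p = 0.13), MED10 (-0.11, 0.32) and Spargel (0.32, 0.0547), and quantile normalization that of Hsp23 (-0.23, 0.196). Dcr-1 lost its call without larval replicate 2 (limma adjusted p = 0.0541) and wild-type pupal replicate 2 (0.108). grim no longer passed without wild-type pupal replicate 2 (limma adjusted p = 0.0577). The apoptosis list lost its call without larval replicate 1 (camera adjusted p = 0.071) and wild-type pupal replicate 2 (0.052).

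The 10 largest increases were genes with almost no larval signal, among them the ecdysone-induced late genes of the Eig71E cluster. Eig71Ea (FBgn0004588, 3L 15642220 to 15642761), of a cluster known from the prepupal salivary gland, was listed at 0 in both larval libraries and at 41.6 and 11.9 FPKM in the pupal ones. Eig71Ed (28.9 and 7.3 FPKM in pupae), Eig71Eb (24.7 and 5.81), Eig71Eg (20.5 and 5.24) and Eig71Ec (23.6 and 4.3) were also listed at 0 in both larval libraries, as were CG4151 (30.1 and 6.996), CG42717 (20.2 and 7.53) and CG32762 (22.5 and 5.85). PGRP-SB2, a peptidoglycan-recognition gene, stood at 0.0927 and 0 FPKM in larvae and 36.5 and 13.5 in pupae, and CG43679 at 0 and 0.408 in larvae and 37.5 and 12.2 in pupae. The limma adjusted p of these 10 genes ran from 0.00152 to 0.00591, and each was higher in wild-type pupal replicate 1 than in replicate 2. The 10 largest decreases were led by the cuticle protein gene Cpr76Bc, which fell by 3.81 (SE 0.30, limma adjusted p = 0.00131), from 94.3 ± 20.4 to 6.05 ± 2.96 FPKM. CG9666 fell by 3.27 (limma adjusted p = 0.00187), CG14933 fell by 2.61 (limma adjusted p = 0.000412), Sip1 fell by 2.12 (limma adjusted p = 0.00131) and the glutathione transferase gene GstD1 fell by 2.07 (limma adjusted p = 0.00131). The others were CG13023 (-1.60), GstD3 (-1.58), mRpL34 (-1.46), CG7267 (-1.45) and IM14 (-1.44), with adjusted p up to 0.0156. The call of IM14 also ended with the length trend removed (-0.82, limma adjusted p = 0.157). IM14 lost its call without wild-type pupal replicate 2 (limma adjusted p = 0.073). For IM14, the log2 fold change was -0.88 without larval replicate 1.

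Markers of other cell types were measured beside these groups. Neuron markers rose in 7 of 8 tested genes and fell in 0 (7 and 0 adjusted over the list alone), with a median of 1.17, a camera adjusted p of 0.00144 and adjusted p = 0.371 with an estimated correlation. Without the length trend 3 were higher and 0 lower, at a median of 0.74 (camera adjusted p = 0.00655, and adjusted p = 0.55 with an estimated correlation). The pan-neuronal gene elav stood at 15.3 and 11.8 FPKM in larvae and at 39.5 and 61.8 in wild-type pupae (1.81, limma adjusted p = 0.00168), and the synaptic gene n-syb at 1.08 and 2.08 in larvae and 4.25 and 8.25 in pupae (1.46, limma adjusted p = 0.00745). All 16 neuron markers, tested or not, were higher in wild-type pupal replicate 2 than in replicate 1. Glial markers had 1 higher and 0 lower of 5 (0 and 0 adjusted over the list alone, camera adjusted p = 0.251), and the glial transcription factor gene repo stayed between 0.0992 and 0.834 FPKM in the 6 libraries. For haemocytes and fat body 1 marker each was tested. The scavenger receptor gene crq was lower in pupae (-0.30, limma adjusted p = 0.0446) and Lsp1gamma did not pass (-0.12, limma adjusted p = 0.624), while the haemocyte gene Hml did not exceed 0.138 FPKM and the fat body gene Lsp2 did not exceed 0.249. Median-of-ratios scaling (0.0769), quantile normalization (0.051) and removal of the length trend (limma adjusted p = 0.141) also ended the call of crq. crq lost its call without larval replicate 1 (limma adjusted p = 0.142), wild-type pupal replicate 1 (0.115), wild-type pupal replicate 2 (0.149), med27 RNAi replicate 1 (0.0748) and med27 RNAi replicate 2 (0.0746). For crq, the log2 fold change was -0.18 without larval replicate 1.

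Over all 6992 tested genes, 3441 differed between pupal and larval wild-type neuroblasts by limma, 1590 higher and 1851 lower in pupae, and 404 of these by at least 2-fold (323 higher and 81 lower). Both replicates of 1 group lay above both of the other in 77.03% of tested genes, against 33.3% by chance. Without larval replicate 2 the count was 2234 and without wild-type pupal replicate 2 it was 1917, and with the length trend removed it was 2117, of which 1495 were called in the same direction in both fits and 43 in opposite directions. Larval and pupal libraries shared 0 flow cells by the run identifiers of the deposited tables, so stage and flow cell cannot be told apart.

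**Figure D2:**
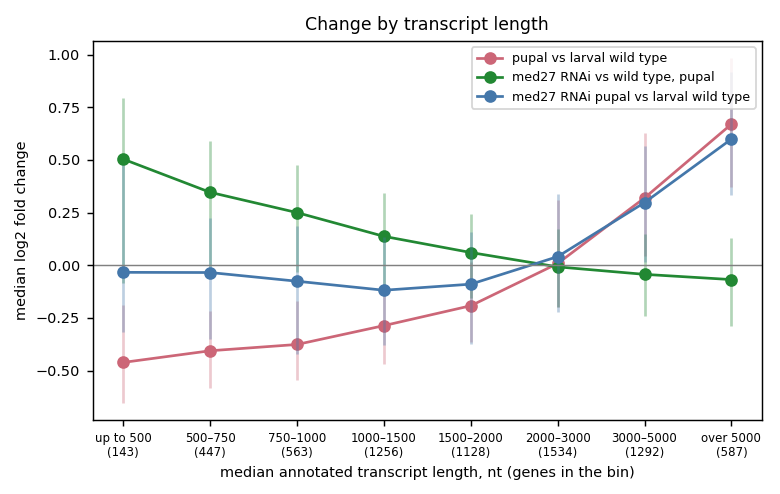
The plot gives the median log2 fold change of genes grouped by annotated transcript length in nt, with the number of genes under each group, as points for each of the 3 comparisons and thin lines for the middle 50% of genes. From larval to pupal wild type the median ran from -0.46 in the shortest group to 0.67 in the longest, and from wild-type to med27 RNAi pupae it ran from 0.50 to -0.07.

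The comparison of med27 RNAi with wild-type pupal neuroblasts asked which transcripts depend on this Mediator subunit at the same stage. Oxidative phosphorylation genes rose in the RNAi libraries. Complex I subunits rose in 27 of 32 tested members and fell in 0 (30 and 1 adjusted over the list alone), with a median of 0.52 and a camera adjusted p of 1.19e-09. In complex III with cytochrome c 8 of 9 rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 6.38e-05), in complex IV 8 of 9 (9 and 0, camera adjusted p = 0.000359) and in complex V 12 of 13 (12 and 0, camera adjusted p = 1.71e-05). These 4 lists had adjusted p = 0.465 with an estimated correlation. Complex II did not pass (camera adjusted p = 0.137), with 3 of 4 higher and 0 lower (3 and 0 adjusted over the list alone), and SdhA at -0.01 (limma adjusted p = 0.947). In complex I, CG9140 (ND-51) rose by 0.72 (limma adjusted p = 0.00151) and CG12859 (ND-B15) from 134 ± 1.94 to 250.0 ± 7.01 FPKM, by 0.89 (limma adjusted p = 0.00161). RFeSP of complex III rose by 0.60 (limma adjusted p = 0.00232), CoVb (COX5B) of complex IV by 0.58 (limma adjusted p = 0.00227) and ATPsyn-Cf6 (ATPsynCF6) of complex V by 0.92 (limma adjusted p = 0.00109). With the length trend removed the medians were 0.17, 0.26 and 0.34 for complexes I, III and V (camera adjusted p = 0.00031, 0.00331 and 0.00358, and adjusted p = 0.579 for each with an estimated correlation), and the call of complex IV ended at 0.14 (camera adjusted p = 0.461). Called members then numbered 11 higher and 1 lower in complex I, 5 and 0 in complex III, 1 and 0 in complex IV, and 8 and 1 in complex V.

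In RNAi pupae mitochondrial ribosomal proteins rose, and the cytosolic list passed as lower with most members not called. Mitochondrial ribosomal proteins rose in 52 of 73 members and fell in 1 (56 and 1 adjusted over the list alone), with a median of 0.43, a camera adjusted p of 6.69e-12 and adjusted p = 0.465 with an estimated correlation. Among them mRpL34 rose from 69.9 ± 0.265 to 162 ± 6.2 FPKM, by 1.20 (SE 0.08, limma adjusted p = 0.000522), mRpL42 by 0.90 (limma adjusted p = 0.00123) and mRpS18A by 0.79 (limma adjusted p = 0.00127). Cytosolic ribosomal proteins were lower in 12 and higher in 3 of 84 (4 and 3 adjusted over the list alone), with a median of -0.19, a camera adjusted p of 1.15e-06 and adjusted p = 0.683 with an estimated correlation, and this call ended under quantile normalization, at a median of -0.04 (camera adjusted p = 0.316). RpS3A fell by 0.71 (limma adjusted p = 0.00363). The paralogues RpS19b and RpS10a, scored beside close copies and so uncertain, rose by 2.07 (limma adjusted p = 0.00154) and 1.94 (limma adjusted p = 0.00177), and RpS5b fell by 0.93 (limma adjusted p = 0.00703). With the length trend removed, 73 cytosolic members were lower and 2 higher, at a median of -0.49 (camera adjusted p = 3.43e-24, and adjusted p = 0.579 with an estimated correlation). Mitochondrial members then had 19 higher and 2 lower, at a median of 0.14 (camera adjusted p = 0.00225, and adjusted p = 0.579 with an estimated correlation).

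Central carbon metabolism changed gene by gene. In the tricarboxylic acid cycle 7 members rose and 5 fell of 17 (9 and 5 adjusted over the list alone, camera adjusted p = 0.2998). The citrate synthase gene kdn rose by 1.02 (limma adjusted p = 0.00254) and CG5261 (muc), of pyruvate dehydrogenase, by 0.86 (limma adjusted p = 0.00231). In glycolysis 3 of 12 rose and 3 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.724, median 0.07, mean -0.21, test down). ImpL3, the lactate dehydrogenase gene, stood at 102 and 8.23 FPKM in wild-type and 2.21 and 3.21 in RNAi pupae, a change of -3.07 (SE 0.94, limma adjusted p = 0.0478) whose size depends on the replicate at 102 FPKM. Without that replicate the call held, at -1.33 (limma adjusted p = 0.0313). The aldolase gene Ald fell by 1.18 (limma adjusted p = 0.0267). In the pentose phosphate pathway 2 of 7 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.948, median -0.20, mean 0.04, test down), and Tal (Taldo) rose by 0.96 (limma adjusted p = 0.00131). Fatty acid oxidation genes rose in 2 and fell in 1 of 9 (2 and 1 adjusted over the list alone, camera adjusted p = 0.947, and 1 and 2 with the length trend removed). Regulators of mitochondrial biogenesis had 0 higher and 1 lower of 6 (0 and 1 adjusted over the list alone, camera adjusted p = 0.948, median 0.05, mean 0.01, test down), with ewg lower at -0.59 (limma adjusted p = 0.0242). Quantile normalization also ended the call of ImpL3 (limma adjusted p = 0.0725). ImpL3 lost its call without larval replicate 1 (limma adjusted p = 0.0746), larval replicate 2 (0.0749), med27 RNAi replicate 1 (0.143) and med27 RNAi replicate 2 (0.12). Ald no longer passed without wild-type pupal replicate 1 (limma adjusted p = 0.0635) and med27 RNAi replicate 2 (0.132). The call of ewg ended without wild-type pupal replicate 2 (limma adjusted p = 0.104), med27 RNAi replicate 1 (0.112) and med27 RNAi replicate 2 (0.0811). For Ald, the log2 fold change was -0.69 without wild-type pupal replicate 1. For ImpL3, the log2 fold change was -1.33 without wild-type pupal replicate 1 and -4.81 without wild-type pupal replicate 2. For ewg, the log2 fold change was -0.37 without wild-type pupal replicate 2.

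Several neuroblast genes that were higher in wild-type pupae than in larvae were lower in RNAi pupae. The proneural gene ase fell from 83.9 ± 2.56 to 47.2 ± 0.0519 FPKM, a log2 fold change of -0.82 (SE 0.10, limma adjusted p = 0.00224), and chinmo from 18.6 ± 3.62 to 9.38 ± 0.822, a log2 fold change of -0.91 (limma adjusted p = 0.00961). CG17838 (Syp) fell by 0.94 (limma adjusted p = 0.0209) and svp fell by 0.38 (limma adjusted p = 0.023), while Imp was at -0.76 (limma adjusted p = 0.0543) and br at -0.50 (limma adjusted p = 0.0814) and neither passed. Of the temporal factors, 0 of 8 rose and 3 fell (0 and 5 adjusted over the list alone), with a median of -0.59, a camera adjusted p of 0.000838 and adjusted p = 0.465 with an estimated correlation. Neuron markers moved the same way, with a median of -0.41, but did not pass (camera adjusted p = 0.0653), and the authors' deposited table held elav (-0.45), cac (-0.71), nrv3 (-1.05) and VGlut (-1.53) as lower. The identity list did not pass, with 2 higher and 5 lower of 20 (2 and 6 adjusted over the list alone, camera adjusted p = 0.0523). Within it sna, a Snail-family gene, rose by 1.55 (limma adjusted p = 0.00336) and pros fell by 0.56 (limma adjusted p = 0.0266), while grh (-0.40, limma adjusted p = 0.051), mira (-0.18, limma adjusted p = 0.151) and dpn (0.12, limma adjusted p = 0.303) did not pass. svp lost its call without wild-type pupal replicate 1 (limma adjusted p = 0.0634), wild-type pupal replicate 2 (0.114), med27 RNAi replicate 1 (0.133) and med27 RNAi replicate 2 (0.095). CG17838 no longer passed without wild-type pupal replicate 1 (limma adjusted p = 0.0534), wild-type pupal replicate 2 (0.0961), med27 RNAi replicate 1 (0.0903) and med27 RNAi replicate 2 (0.0578). The call of pros ended without wild-type pupal replicate 2 (limma adjusted p = 0.0991), med27 RNAi replicate 1 (0.117) and med27 RNAi replicate 2 (0.0824). chinmo lost its call without wild-type pupal replicate 2 (limma adjusted p = 0.0558) and med27 RNAi replicate 1 (0.0535). For pros, the log2 fold change was -0.33 without wild-type pupal replicate 2.

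Ecdysone-response genes were lower as a list, with 0 of 15 members higher and 2 lower (0 and 2 adjusted over the list alone), a median of -0.34, a camera adjusted p of 0.000359 and adjusted p = 0.465 with an estimated correlation. The members that fell were ImpL2 (-0.84, limma adjusted p = 0.0071), which encodes a secreted binding protein for insulin-like peptides, and ftz-f1 (-0.65, limma adjusted p = 0.0302), a nuclear receptor gene. EcR (-0.13, limma adjusted p = 0.532) and Eip75B (-0.06, limma adjusted p = 0.829) did not pass. Insulin and TOR genes had 0 higher and 2 lower of 15 (0 and 2 adjusted over the list alone, camera adjusted p = 0.36, median 0.03, mean -0.17, test down). The members that fell were Thor (FBgn0261560, 2L 3478434 to 3479612), the translation repressor 4E-BP, from 39.3 ± 12.4 to 9.83 ± 2.33 FPKM (-1.88, limma adjusted p = 0.00345), and foxo (-0.82, limma adjusted p = 0.00673). InR (0.04, limma adjusted p = 0.913) did not pass. The growth regulator dm did not pass either (-0.19, limma adjusted p = 0.634), and its ribosome biogenesis list had 5 higher and 0 lower of 14 (5 and 0 adjusted over the list alone, camera adjusted p = 0.0561). In the cell cycle list 2 rose and 4 fell of 31 (2 and 4 adjusted over the list alone, camera adjusted p = 0.518, median 0.08, mean -0.02, test down). Cdk4 fell by 0.91 (limma adjusted p = 0.00356), CycE fell by 0.54 (limma adjusted p = 0.0163) and stg fell by 0.39 (limma adjusted p = 0.0327). ftz-f1 lost its call without wild-type pupal replicate 1 (limma adjusted p = 0.0967), wild-type pupal replicate 2 (0.103), med27 RNAi replicate 1 (0.119) and med27 RNAi replicate 2 (0.102). stg no longer passed without wild-type pupal replicate 2 (limma adjusted p = 0.167), med27 RNAi replicate 1 (0.0967) and med27 RNAi replicate 2 (0.167). The call of CycE ended without wild-type pupal replicate 2 (limma adjusted p = 0.0843), med27 RNAi replicate 1 (0.0859) and med27 RNAi replicate 2 (0.0618).

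The other Mediator subunits mostly rose where they changed. Of 29 subunits 12 were higher and 1, MED27 itself, lower (16 and 1 adjusted over the list alone), with a median of 0.25, a camera adjusted p of 0.00449 and adjusted p = 0.465 with an estimated correlation. Without the length trend 7 were higher and 1 lower, at a median of 0.13 (camera adjusted p = 0.0291, and adjusted p = 0.579 with an estimated correlation). MED10 rose by 0.63 (limma adjusted p = 0.00255), MED19 by 0.60 (limma adjusted p = 0.00295) and MED22 by 0.60 (limma adjusted p = 0.00547). The RNA interference list had 2 higher and 0 lower of 6 (2 and 0 adjusted over the list alone, camera adjusted p = 0.724). These were Dcr-2 (0.69, limma adjusted p = 0.0208) and AGO2 (0.47, limma adjusted p = 0.00725), of the small interfering RNA pathway. The stress list was lower, with 1 rising and 5 falling of 15 (1 and 5 adjusted over the list alone), a median of -0.17, a camera adjusted p of 0.0300 and adjusted p = 0.592 with an estimated correlation. That call ended under median-of-ratios scaling (camera adjusted p = 0.0523), quantile normalization (0.151) and removal of the length trend (0.0583). Hsp68 fell by 1.09 (limma adjusted p = 0.00597), Hsp70Ba fell by 1.10 (limma adjusted p = 0.000778) with the same doubt over near-identical copies, and GstD1 rose by 1.08 (limma adjusted p = 0.00712). Apoptosis genes had 1 higher and 0 lower of 8 (1 and 0 adjusted over the list alone, camera adjusted p = 0.724), the caspase gene Dcp-1 rising by 0.72 (limma adjusted p = 0.00796). Autophagy genes had 1 higher and 0 lower of 13 (0 and 0 adjusted over the list alone, camera adjusted p = 0.948). Removal of the length trend ended the call of MED22 (0.24, limma adjusted p = 0.0934), and quantile normalization that of Dcr-2 (0.46, 0.128). Dcr-2 lost its call without wild-type pupal replicate 1 (limma adjusted p = 0.0745), wild-type pupal replicate 2 (0.073) and med27 RNAi replicate 2 (0.117). AGO2 no longer passed without med27 RNAi replicate 1 (limma adjusted p = 0.0594). The call of Dcp-1 ended without med27 RNAi replicate 2 (limma adjusted p = 0.0635). The heat shock list lost its call without wild-type pupal replicate 1, at a median of -0.06, and without med27 RNAi replicate 1, at -0.13.

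**Figure D3:**
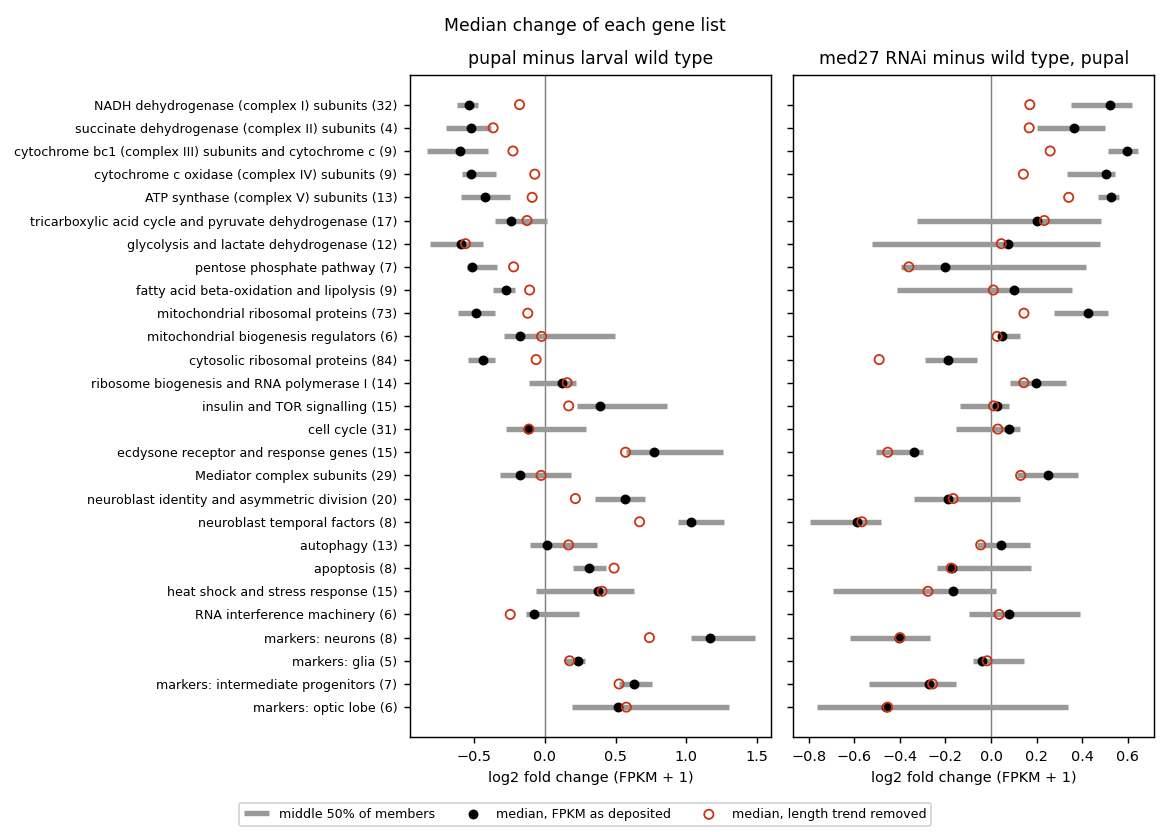
For each of the 27 tested gene lists, with the number of tested members in brackets, the plot gives the median log2 fold change of FPKM + 1 as a black point, the middle 50% of members as a grey bar and the median with the transcript length trend removed as an open red circle, for pupal minus larval wild type (left) and med27 RNAi minus wild-type pupae (right). The complex I median was -0.54 on the left and 0.52 on the right, and -0.18 and 0.17 with the trend removed. For cytosolic ribosomal proteins these were -0.44 and -0.19, and -0.06 and -0.49.

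The 10 largest increases in RNAi pupae were led by His2B:CG17949, from 10.7 ± 0.739 to 197 ± 73.8 FPKM (4.04, limma adjusted p = 0.000522), a histone gene with near-identical copies whose value is therefore uncertain. CG17018 (Marf1) rose by 3.48 (limma adjusted p = 0.000935), CG6426 by 3.32 (limma adjusted p = 0.000522), CG31477 by 3.18 (limma adjusted p = 0.00154) and CG41503, which shares sequence with a copy elsewhere and is uncertain, by 3.16 (limma adjusted p = 0.00232). The others were CG32364 (2.76), the lipocalin gene GLaz (2.50), Rcd-1r (2.47), del (2.43) and CG15343 (2.35), with adjusted p up to 0.0163. The 10 largest decreases were ImpL3, MED27 and Thor, given above, and the antibacterial peptide gene CecA1 (-2.37, limma adjusted p = 0.00252), CG12171 (-2.12, limma adjusted p = 0.00223), CG7054 (-2.11, limma adjusted p = 0.00204), CG10424 (-2.05, limma adjusted p = 0.000522), CG17680 (-1.95, limma adjusted p = 0.000626), CG5783 (-1.94, limma adjusted p = 0.00587) and CR43283. CR43283 (lncRNA:cherub, FBgn0262972, 3R 7073825 to 7081845), a long non-coding RNA of neuroblasts, fell from 5984 ± 326 to 1645 ± 519 FPKM, a log2 fold change of -1.90 (SE 0.36, limma adjusted p = 0.00874). Rcd-1r lost its call without wild-type pupal replicate 1 (limma adjusted p = 0.0537) and wild-type pupal replicate 2 (0.0668). For Rcd-1r, the log2 fold change was 1.45 without med27 RNAi replicate 2.

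Among markers of other cell types, the neuron list did not pass in this comparison, with 0 higher and 0 lower of 8 (0 and 0 adjusted over the list alone), a median of -0.41 and a camera adjusted p of 0.0653. In RNAi pupae elav stood at 36.7 and 43.1 FPKM (-0.30, limma adjusted p = 0.32). Glial markers had 0 higher and 1 lower of 5 (0 and 1 adjusted over the list alone, camera adjusted p = 0.518), the 1 being the glutamate transporter gene Eaat1, which fell from 66.3 ± 7.36 to 18.7 ± 0.0409 FPKM (-1.77, limma adjusted p = 0.000522). Intermediate progenitor markers had 0 higher and 2 lower of 7 (0 and 2 adjusted over the list alone), a camera adjusted p of 0.0433 and adjusted p = 0.465 with an estimated correlation. The members that fell were pnt (-0.68, limma adjusted p = 0.00804) and D (-0.72, limma adjusted p = 0.0125). The list's call ended under median-of-ratios scaling (camera adjusted p = 0.0807), quantile normalization (0.314), removal of the length trend (0.178), technical run 2 alone (0.0516) and over genes of at least 5 FPKM (0.0618). The optic lobe list did not pass (camera adjusted p = 0.137), with 1 higher and 3 lower of 6 (2 and 3 adjusted over the list alone), and slp2 fell by 0.81 (limma adjusted p = 0.00257) and Optix fell by 0.64 (limma adjusted p = 0.00444). The haemocyte marker crq fell by 0.50 (limma adjusted p = 0.0119) and the fat body marker Lsp1gamma did not pass (-0.27, limma adjusted p = 0.324). crq lost its call without wild-type pupal replicate 2 (limma adjusted p = 0.0566) and med27 RNAi replicate 2 (0.0831). D no longer passed without wild-type pupal replicate 2 (limma adjusted p = 0.0718), med27 RNAi replicate 1 (0.061) and med27 RNAi replicate 2 (0.0578). The call of pnt ended without med27 RNAi replicate 1 (limma adjusted p = 0.061) and med27 RNAi replicate 2 (0.051). The intermediate progenitor list lost its call without wild-type pupal replicate 2 (camera adjusted p = 0.134) and med27 RNAi replicate 1 (0.0951).

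Of the 6992 tested genes 1977 differed between RNAi and wild-type pupae by limma, 1373 higher and 604 lower, and 221 by at least 2-fold (117 higher and 104 lower). The higher share was 69.4% as deposited, 56.7% of 1818 calls under median-of-ratios scaling, 52.9% of 1661 under quantile normalization and 51.8% of 1877 with the length trend removed. Both replicates of 1 group lay above both of the other in 71.4% of genes, against 33.3% by chance. The count was 968 without wild-type pupal replicate 2, 938 without med27 RNAi replicate 1 and 728 without replicate 2. Without the filter on low values 1315 of 11797 genes passed, and by limma adjusted p chinmo (0.0533), svp (0.053), CR43283 (0.059), CycE (0.0624), stg (0.0871), pros (0.0923), CG17838 (0.0962) and ImpL3 (0.167) did not.

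The comparison of med27 RNAi pupal with wild-type larval neuroblasts asked how far the RNAi cells stood from the earlier stage. The ecdysone list did not pass here, while of single genes Hr4 was higher in the RNAi pupae by 2.80 (SE 0.11, limma adjusted p = 0.000102), Eip75B by 1.68 (limma adjusted p = 0.000886) and InR by 1.70 (limma adjusted p = 0.00143). Cytosolic ribosomal proteins fell in 73 of 84 members and rose in 2 (75 and 2 adjusted over the list alone), with a median of -0.65, a camera adjusted p of 6.44e-20 and adjusted p = 0.77 with an estimated correlation, and the call ended under quantile normalization, at a median of -0.09 (camera adjusted p = 0.0982). RpL39 fell by 1.57 (limma adjusted p = 0.000642), RpS3A fell by 1.12 (limma adjusted p = 0.000571) and RpL10Ab fell by 1.11 (limma adjusted p = 0.000571), while RpS19b rose by 2.52 (limma adjusted p = 0.000571). Glycolysis genes fell in 5 and rose in 0 of 12 (5 and 0 adjusted over the list alone), with a camera adjusted p of 0.0183 and adjusted p = 0.77 with an estimated correlation, and Gapdh1 fell by 1.08 (limma adjusted p = 0.00254) and Ald fell by 1.97 (limma adjusted p = 0.00238). Neuroblast identity genes rose in 15 and fell in 1 of 20 (15 and 1 adjusted over the list alone), with a camera adjusted p of 0.0183 and adjusted p = 0.77 with an estimated correlation. Among them sna rose by 2.05 (limma adjusted p = 0.000766) and HLHmgamma fell by 0.77 (limma adjusted p = 0.00064). With the length trend removed the calls of glycolysis (camera adjusted p = 0.0686) and neuroblast identity (0.655) ended, the latter with 5 higher and 3 lower at a median of 0.05. The glycolysis list lost its call without larval replicate 2 (camera adjusted p = 0.0718). The neuroblast identity list lost its call without larval replicate 2 (camera adjusted p = 0.0869).

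The other tested lists did not pass in this comparison. Complex I had 2 higher and 6 lower of 32 (2 and 3 adjusted over the list alone), with a median of -0.05 (camera adjusted p = 0.266), and mitochondrial ribosomal proteins had 3 higher and 19 lower of 73 (0 and 4 adjusted over the list alone), with a median of -0.05 (camera adjusted p = 0.0831). The balance turned without the length trend, to 6 higher and 3 lower at a median of 0.03 for complex I and 12 and 10 at 0.03 for mitochondrial ribosomal proteins, and ecdysone-response genes had 3 and 3. Ecdysone-response genes had 4 higher and 1 lower of 15 (camera adjusted p = 0.311) and temporal factors 2 higher and 0 lower of 8 (camera adjusted p = 0.198), the same counts as those adjusted over the list alone. Median, mean and test differed in sign for the tricarboxylic acid cycle (0.09, 0.00477, down), mitochondrial biogenesis regulators (-0.06, 0.09, down) and the cell cycle (-0.07, 0.01, down). Of single genes, dm rose by 1.28 (limma adjusted p = 0.00794), kdn by 1.44 (limma adjusted p = 0.000571), the neuron marker elav by 1.502 (limma adjusted p = 0.00175) and svp by 0.72 (limma adjusted p = 0.00125). Temporal factors chinmo (0.44, limma adjusted p = 0.0711), CG17838 (0.29, limma adjusted p = 0.314), Imp (0.21, limma adjusted p = 0.506) and br (0.47, limma adjusted p = 0.0688) did not pass, nor did ase (-0.15, limma adjusted p = 0.252), mira (0.02, limma adjusted p = 0.833), EcR (-0.38, limma adjusted p = 0.0647), stg (0.06, limma adjusted p = 0.683) or ImpL3 (-2.05, limma adjusted p = 0.111). By limma pros (0.57, limma adjusted p = 0.0153), CycE (0.39, limma adjusted p = 0.0334), grh (0.38, limma adjusted p = 0.0406) and dpn (0.23, limma adjusted p = 0.0493) rose, but with the length trend removed pros was at -0.43 (limma adjusted p = 0.00617) and the calls of CycE (0.11, 0.398), grh (-0.00148, 0.992) and dm (0.69, 0.0521) ended. Median-of-ratios scaling ended the calls of CycE (limma adjusted p = 0.0901), grh (0.103) and dpn (0.151), and so did quantile normalization (0.0929, 0.103 and 0.184). Eaat1 (-1.81, limma adjusted p = 0.000311) and Idh (-1.23, limma adjusted p = 0.000500) fell. pros lost its call without larval replicate 2 (limma adjusted p = 0.0802) and med27 RNAi replicate 2 (0.0848). CycE no longer passed without larval replicate 2 (limma adjusted p = 0.103), med27 RNAi replicate 1 (0.0734) and med27 RNAi replicate 2 (0.16). The call of grh ended without larval replicate 2 (limma adjusted p = 0.113), wild-type pupal replicate 1 (0.0565), wild-type pupal replicate 2 (0.0567), med27 RNAi replicate 1 (0.0881) and med27 RNAi replicate 2 (0.177). dpn lost its call without larval replicate 2 (limma adjusted p = 0.156), wild-type pupal replicate 1 (0.0648), wild-type pupal replicate 2 (0.0645), med27 RNAi replicate 1 (0.112) and med27 RNAi replicate 2 (0.26). For grh, the log2 fold change was 0.57 without larval replicate 1 and 0.18 without larval replicate 2. For CycE, the log2 fold change was 0.21 without larval replicate 2.

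Of the 6992 tested genes 3313 differed between RNAi pupal and larval neuroblasts by limma, 1947 higher and 1366 lower, and 586 by at least 2-fold (342 higher and 244 lower). The higher share of 58.8% was 48.9% of 3326 calls under median-of-ratios scaling and 49.5% of 3211 under quantile normalization. Both replicates of 1 group lay above both of the other in 77.7% of genes, against 33.3% by chance. The count was 1614 without med27 RNAi replicate 2, and here too stage and flow cell cannot be told apart.

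The wild-type stage change and the RNAi change were then set against each other gene by gene, to ask whether RNAi moved genes back along the larva-to-pupa change. Of the genes that fell from larva to pupa, 704 rose in RNAi pupae, where independent lists of the same sizes would share 363, and 211 of those that rose then fell, against 137. In the concordant directions 120 genes rose in both, against 312, and 129 fell in both, against 160. Both changes use the wild-type pupal libraries, so chance alone makes them opposite, and with 2 such libraries no split leaves 2 in each part, so part of the excess may come from the shared controls. Across genes, which are not independent replicates, Pearson's r was -0.29, while 100 simulated data sets without any effect gave r from -0.56 to -0.45. The covariance, which shared controls shift by the same amount with or without effects, was -0.0715 against a simulated mean of -0.0122 (-0.0152 to -0.0101), a difference of -0.0593. The difference was -0.0371 without wild-type pupal replicate 2, -0.108 without replicate 1 and -0.0295 with the length trend removed.

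**Figure D4:**
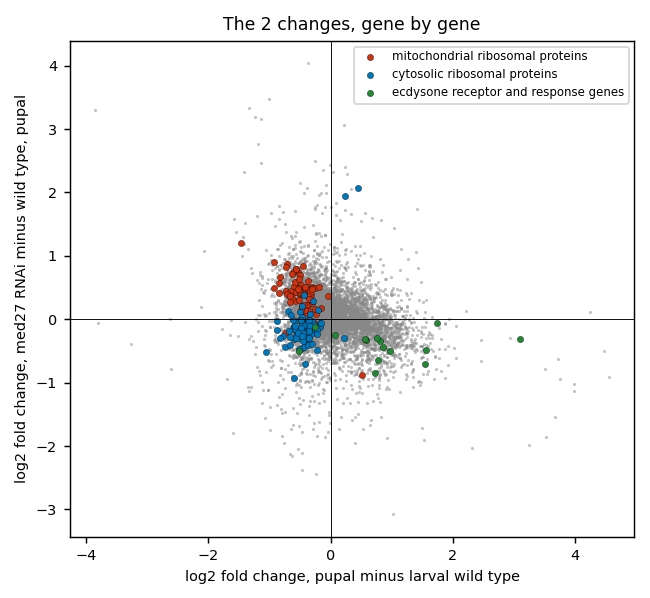
Each point is 1 of the 6992 tested genes, placed by its log2 fold change from larval to pupal wild type (horizontal) and from wild-type to med27 RNAi pupae (vertical), with mitochondrial ribosomal proteins, cytosolic ribosomal proteins and ecdysone-response genes in colour. Mitochondrial ribosomal proteins had medians of -0.49 and 0.43 on these axes and ecdysone-response genes 0.77 and -0.34. Cytosolic ribosomal proteins had -0.44 and -0.19 (-0.06 and -0.49 without the length trend).

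The authors' own comparisons were deposited as lists of genes below a false discovery rate of 0.01. For pupal against larval wild type, the authors' deposited table held 1958 genes, 1379 higher and 579 lower in pupae, 37 of them with an infinite fold change. Of the 1750 with a finite value and a limma value here, 1749 had the same sign, the fold changes correlated across genes at r = 0.94, and 1663 were also called here. For med27 RNAi against wild-type pupae, the authors' deposited table held 1597 genes, 813 higher and 784 lower, 12 of them infinite, and 1463 of 1463 had the same sign, with r = 0.96 and 1193 also called here. The authors' deposited table gave log2 fold changes of -3.63 for MED27, -4.45 for ImpL3, -2.06 for Thor, -1.87 for Eaat1, -1.08 for chinmo, -0.87 for ase and 1.01 for mRpL34 in RNAi against wild-type pupae. For pupal against larval wild type the authors' deposited table gave 3.18 for Hr4, 1.97 for Eip75B, 1.95 for InR, 1.75 for chinmo, 1.76 for ImpL3 and -1.07 for mRpL34.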

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

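Removal of the length trend and of genes with a failed estimate were chosen only after the results were seen, and all other settings before. The direction of each called list was the same under every setting in which it was run, and the neuron markers, called for pupal against larval wild type, were not run over genes of at least 5 FPKM. The cause of the changes given here was not tested unless a setting's construction shows it. A false discovery rate of 0.01 is stricter by construction and gave 1803 genes for pupal against larval wild type, 834 for RNAi against wild-type pupae and 1882 for RNAi pupae against larvae, where 0.05 gave 3441, 1977 and 3313. Without a filter, which adds genes to the adjustment, RNAi against wild-type pupae gave 1315. With the length trend removed, pupal against larval wild type gave 2117. Leaving out 1 replicate, which leaves fewer samples, gave 1917 to 3469, 728 to 2254 and 1614 to 3270 genes for these comparisons, 29 to 34 called lists where all replicates gave 31, and a covariance of the stage and RNAi changes of -0.128 to -0.0564. The numbers 1 and 2 of the replicates pair nothing by the labels, and same-numbered deviations correlated at -0.0572, -0.0256 and -0.104 in the 3 comparisons. With the replicate number as a block, 3035, 1537 and 2938 genes and 30 lists were called and the covariance was -0.0715.

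Log2 fold changes that turned sign were the following. For RNAi against wild-type pupae, median-of-ratios scaling gave tam -0.0281 and InR -0.0400, quantile normalization gave InR -0.00819, TFAM -0.0785, nrv2 -0.0853 and dpn -0.14, and removal of the length trend gave TFAM -0.0134. Leaving out 1 replicate gave ranges of -0.0126 to 0.11 for tam, -0.24 to 0.32 for InR, -0.0441 to 0.0288 for SdhA and -0.22 to 0.0911 for Eip75B. The ranges were -0.62 to 0.0120 for elav, -0.13 to 0.0490 for loco and -0.46 to 0.0802 for dm. For pupal against larval wild type, gcm was -0.20 under quantile normalization, with a range of -0.12 to 0.58 over left-out replicates, where ImpL3 ranged from -0.73 to 2.76. Removal of the length trend gave Dcr-1 -0.34 (0.35 as deposited, both called), r2d2 0.10 and MED27 0.0662. For RNAi pupae against larvae, median-of-ratios scaling gave stg -0.0106 and mira -0.0435, and quantile normalization gave Hsp23 0.0733. Leaving out 1 replicate gave -0.0365 to 0.15 for stg, -0.0469 to 0.0945 for mira, -0.0879 to 0.68 for CG17838, -0.21 to 0.15 for SdhC, -0.20 to 0.0267 for cype and -0.16 to 0.57 for Imp. Removal of the length trend gave stg -0.0334, mira -0.12, SdhC 0.0611, Imp -0.13, pros -0.43, Dcr-1 -0.14, chinmo -0.13, Tor -0.26, grh -0.00148, loco -0.00580 and SdhB 0.00750. Larval values of low genes were the least precise.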

Other observations

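Of the tests of explanations given here, all but that of tio, the neighbour of a transgene landing site of this RNAi collection, were chosen only after the results were seen (quantile normalization and the gene and list tests were fixed before), and with 2 replicates per group their SDs are weak. The neighbourhood of MED27 on 3R was also looked at, with genes picked after their values were seen. Within 25 kb lay 15 genes, of which 13 were tested in RNAi against wild-type pupae. Both counts include MED27 itself. By limma 4 were lower, MED27 among them, and 3 higher. CG12171 (1459346 to 1460362) fell from 22.1 and 14.4 FPKM to 4.41 and 2.49, and had a log2 fold change of -2.12 (SE 0.26, limma adjusted p = 0.00223). The adjacent CG31549 was at -1.55 (limma adjusted p = 0.00632) and CG31548 at -0.83 (limma adjusted p = 0.0211), while between these and MED27 sec23 was at 0.33 (limma adjusted p = 0.0354) and elm at 0.86 (limma adjusted p = 0.000934). On the other side CG2182, which overlaps MED27, stood at 50.3 and 49.6 FPKM in RNAi and 47.2 and 43.6 in wild-type pupae.

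The purine synthesis gene ade3 stood at 62.9 and 55.9 FPKM in wild-type and 20.99 and 13.0 in RNAi pupae (-1.78, limma adjusted p = 0.00166), and ade5, of the same pathway and like ade3 picked after its value was seen, at 23.2 and 23.5 in wild-type and 83.7 and 77.5 in RNAi pupae (1.74, limma adjusted p = 0.000522). The RNA of the dosage compensation gene roX1 was lower in RNAi pupae, at -0.87 (limma adjusted p = 0.00274). The subunit gene MED9 stood at 57.0 and 44.5 FPKM in larvae, 22.5 and 36.7 in wild-type pupae, and 25.7 and 3.26 in RNAi pupae.

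For the changes in RNAi pupae, misexpression of tio from the insertion would have raised it in both RNAi libraries, but tio stood there at a mean of 0.322 FPKM, and each was below both wild-type pupal libraries (0.666 and 1.45, the latter above the bound of 1 set beforehand for every library). For complexes I, III and V and mitochondrial ribosomal proteins, the median went from 0.454 to 0.175 (SD 0.0447) with the length trend removed. These lists stayed past the threshold, though not with an estimated correlation (adjusted p = 0.579). They were grouped by that outcome, without complex IV, so it cannot tell whether the trend was the whole cause. Length alone would not put complex I 0.684 (SD 0.118) above cytosolic ribosomal proteins of similar length. This gap, seen beforehand, cannot decide on a trend in complex I. An effect of MED27 loss on the respiratory and mitochondrial ribosomal protein genes also stays open. Off-target effects of the 1 construct used were not tested.

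Respiratory chain and ribosomal protein genes were lower in pupal than in larval wild type. Quantile normalization, which can itself remove such a change, ended the cytosolic ribosomal protein call. For complexes I to III and mitochondrial ribosomal proteins, the median went from -0.511 to -0.157 (SD 0.0461) with the length trend removed. These lists stayed past the threshold, though not with an estimated correlation. They were grouped by that outcome, so it cannot tell whether the trend was the cause of all of the difference. The trend may account for part of it. Complexes IV and V and cytosolic ribosomal proteins formed the group whose calls ended (largest camera adjusted p = 0.345). Their median went from -0.441 to -0.0557 (SD 0.024). The trend's fit included these members, so their small remainder cannot decide. The trend may account for this part, and its origin, technical or biological, was not tested. Larval and pupal libraries shared 0 flow cells, so a batch effect and the stage cannot be told apart for any of these genes, and a change with stage stays open as well.

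Neuron markers were higher in pupal than in larval wild type. Of 16 markers, 15 were higher in both pupal than in both larval libraries. By chance 16.7% would be, but 77.03% of all tested genes had replicates apart, up or down, so this count is weak. Of the 16, 8 could be tested, and all 16 were higher in wild-type pupal replicate 2 than in replicate 1. Neurons or their fragments among the sorted pupal cells are a candidate, although the gate on large cells with high GFP should remove most neurons. Next to elav at 39.5 and 61.8 FPKM the synaptic genes n-syb and brp reached 4.25 and 8.25, and 0.992 and 2.21. The length trend is argued against as the whole cause, since the difference of the library medians went from 1.13 to 0.863 (SD 0.381) with it removed, although the median log2 fold change went from 1.17 to 0.74, called members from 7 to 3 of 8, and the list had adjusted p = 0.55 with an estimated correlation. Earlier neuronal transcription in the neuroblasts themselves was not tested and stays open, as does the flow cell.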
